A study of Mus musculus with 16 samples.

How the data were processed

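Total RNA of 16 TCL1 leukemias grown in vivo was extracted with a column kit and labelled with biotin as amplified cRNA, per the labels' protocols, which also name a treatment with 4-hydroxytamoxifen for every sample without saying how it was given. GenomeStudio is the tool in the submitters' processing notes, with no version. The deposited non-normalized table holds probe intensity on a linear scale, 1 column per array, with no detection p-values and no control probes. Its columns differ in distribution, so the values had not been normalized between arrays. The deposited series table holds log2 values, and these equalled the quantile-normalized log2 intensity of the other table, with no background correction, within 0.0041. Its median was 6.60 on every array, its scale and centring were settled by this match, and each of the 16 arrays matched its own column best. Every value column belonged to a sample of the series.

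Groups were taken from the BCR type in the labels, 7 anti-Sm and 9 anti-PtC samples, and replicates were numbered only as names. Both groups lay on both slides. The sample numbers in the titles fall in separate ranges for the 2 groups. Any batch that follows this numbering cannot be told apart from the BCR type. Correlations between arrays ran from 0.864 to 0.982, so no 2 arrays held identical values.

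The planned correction by detection p-values could not be run on a table without them, so the fallback written with the plan was used. Intensities were corrected with limma's normexp method with an offset of 50, put on the log2 scale and quantile normalized over all arrays (limma 3.58.1 in R 4.3.3). Normexp with this offset compresses differences near background, so fold changes of dim genes are understated, and quantile normalization stretches the 2 dim arrays to the distribution of the others, noise included. Probes with a mean above the median of all probes were tested, 12848 of 25697, because no detection calls were at hand. Of all probes, 23978 carried 1 gene symbol, and the other 1719 were left unnamed here. Of the symbols, 23962 were matched by gene ID to a RefSeq table of the mouse assembly GRCm38.p6, used only for names and for which genes neighbour each other, and the array's own symbols were kept otherwise. The tested probes with a symbol stood for 8887 genes, 2275 of them with more than 1 probe.

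The difference anti-Sm minus anti-PtC was fitted with lmFit and eBayes without covariates, and p-values were adjusted over all tested probes by the Benjamini-Hochberg method with a threshold of 0.05. For lists, the probe with the highest mean stood for its gene. The 28 gene lists were fixed before the data were examined, as were the groups, the test and the other settings except those said to be added. Of 484 distinct list symbols 429 were on the array and named, and 369 were tested. The 26 lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, two-sided, with adjustment over the lists. The lists of dendritic cell and sex-linked genes had too few members over 16 arrays. Over 14 arrays the dendritic list had 5 and was not called (camera adjusted p = 0.344). Camera with an estimated correlation and fry stood beside it, and an exact permutation of the list mean per array over all 11440 splits was added after seeing the data.

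The rule for named genes, set in advance, took up to 10 genes past the threshold in each direction or, where none passed, the 5 with the smallest p in each direction. It also took up to 3 members with the smallest p from each called list, and Ighm, Ighd, Cd5 and Tcl1. It gave 34 genes with a value above the filter. Genes that passed only without the 2 dim arrays, other than H2-Ea and Eps8, are named outside this rule.

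The procedure was tested on simulated data for this comparison, over 12848 probes on 7 and 9 arrays. It recovered 44% of probes changed by 0.5 on the log2 scale, 88.7% of those changed by 1 and 98.1% of those changed by 2. Of 157 calls 8 were false, and 0 of 25 unchanged lists were called. The simulated probes varied independently of each other, unlike real genes, and no simulated array was dim.

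Alternatives covered no background correction, normexp with an offset of 16, median scaling, cyclic loess, the deposited log2 values, no filter and a filter at the 75th percentile, slide as a block, slide with position, each slide alone, Xist as a covariate, a trended robust variance, array weights, a fold threshold, and each array left out in turn. The runs without the 2 dim arrays, with the offset of 16, with the stricter filter, with exact permutation and without H2-Ea were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.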

Results

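Gene expression was measured in 16 leukemias of TCL1 mice, a transgenic model in which the TCL1 oncogene drives a disease resembling human chronic lymphocytic leukemia. The labels divide them by the specificity of their B cell receptor (BCR): 7 leukemias carried an anti-Sm BCR, directed at a ribonucleoprotein autoantigen, and 9 carried an anti-PtC BCR, directed at phosphatidylcholine. Each leukemia was hybridised to 1 Illumina mouse bead array with 25697 probes. The arrays lay on 2 slides, with 4 anti-Sm and 4 anti-PtC arrays on slide 1 and 3 and 5 on slide 2. The labels do not say whether every array came from a separate mouse, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

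Before normalization, the 95th percentile of probe intensity lay between 733 and 1179 on 14 of the arrays, with medians of 90.6 to 107. On anti-PtC replicate 3 it was 273 and on anti-PtC replicate 8 it was 131, with medians of 79.4 and 71.9. These 2 dim arrays belonged to the same group but to different slides. The counts of probes, genes and called lists are therefore also given without them, a choice made after seeing the data.

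**Figure D1:**
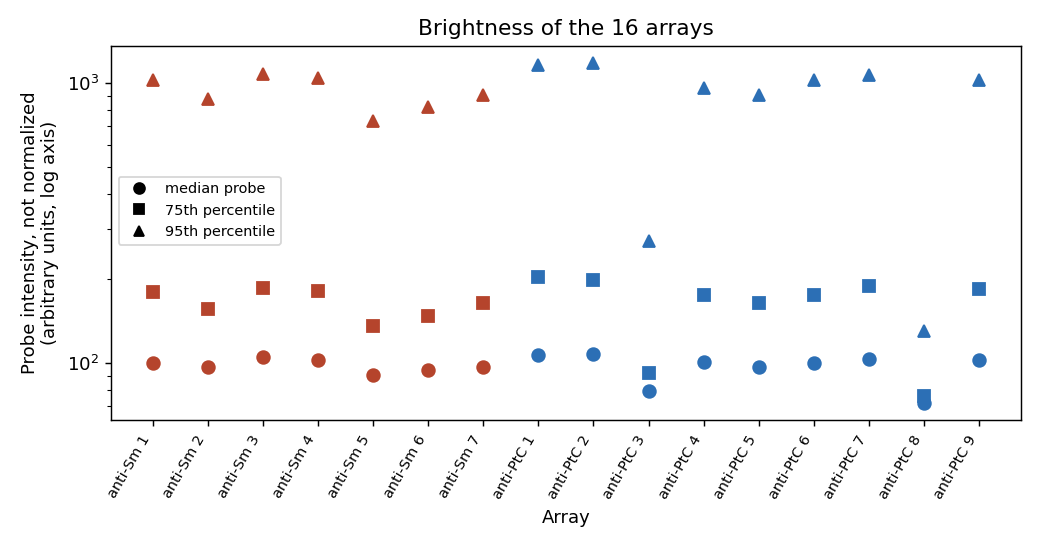
Median, 75th and 95th percentile of probe intensity before normalization (arbitrary units, log axis) on each array, anti-Sm in red and anti-PtC in blue. The 95th percentile of anti-PtC replicates 3 and 8 is 273 and 131, below the range of 733 to 1179 of the other 14 arrays.

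The series asks which genes differ between leukemias with these BCRs. The widest separation was in H2-Ea (probe ILMN_2741935), which encodes the alpha chain of the MHC class II molecule I-E. Its log2 signal was 13.06 ± 0.43 (SD, n = 7) in anti-Sm and 7.67 ± 2.76 (SD, n = 9) in anti-PtC leukemias, a difference of 5.39 (SE 0.97). All 7 anti-Sm arrays lay between 12.44 and 13.58. Of the anti-PtC arrays, 7 lay between 5.79 and 7.19, while the dim replicates 3 and 8 read 12.32 and 12.58. The difference was 5.63 within slide 1, 5.17 within slide 2 and 5.40 with slide as a block. In limma over the 12848 probes tested, H2-Ea did not pass (adjusted p = 0.243), and neither did any other probe: 0 probes and 0 genes had an adjusted p under 0.05, and 746 probes (5.81%) had an unadjusted p under 0.05. With slide as a block the count was also 0. H2-Ea passed when anti-PtC replicate 3 alone was left out (limma adjusted p = 0.0232), H2-Ea and Eps8 passed without anti-PtC replicate 8 alone (adjusted p = 0.0087 for both), and median scaling in place of quantile normalization let H2-Ea and a probe of H2-K1 pass (adjusted p = 0.0045 and 0.0021).

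The genes nearest the threshold therefore stand here as values that did not pass. After H2-Ea, the smallest p-values among genes higher in anti-Sm leukemias belonged to Chst1, a carbohydrate sulfotransferase (log2 difference 1.68, SE 0.31), Nmral1 (1.02, SE 0.20), Carmil2, a regulator of actin capping (0.48, SE 0.10), and Grwd1, a ribosome biogenesis factor (0.68, SE 0.15). All 7 anti-Sm arrays were above the anti-PtC mean for each of these genes. Grwd1 has another probe, which differed by 0.11. Among genes lower in anti-Sm leukemias they belonged to Eps8, an actin-binding signalling adaptor (-0.87, SE 0.14, limma adjusted p = 0.180, the smallest of all), Arhgap27 (-0.53, SE 0.11), Malt1, the paracaspase that links the BCR to NF-kB (-0.88, SE 0.20), Gde1 (-0.65, SE 0.15), and Nsf, an ATPase of vesicle fusion (-0.70, SE 0.16). None of the 7 anti-Sm arrays was above the anti-PtC mean for any of these 5 genes. The remaining Gde1 probes differed by 0.06 and -0.07. Within slides 1 and 2 the differences were 1.30 and 2.22 for Chst1, -1.09 and -0.62 for Eps8, and -0.86 and -0.94 for Malt1.

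Without the 2 dim arrays, 8 probes of 6 genes passed in limma, and 1224 probes (9.53%) had an unadjusted p under 0.05. These 6 genes, other than H2-Ea and Eps8, are named after their values were seen. Leaving out the dim arrays also left out the anti-PtC arrays with high H2-Ea. H2-Ea was higher in anti-Sm leukemias by 6.94 on the log2 scale (SE 0.27, 7 and 7 arrays, adjusted p = 4.5e-09). H2-K1, an MHC class I heavy chain, was higher by 2.23 on probe ILMN_2795520 (SE 0.19, adjusted p = 8.8e-05), but its other probe differed by -0.05 (SE 0.17). Lower in anti-Sm leukemias were Eps8 (-1.09, SE 0.14, adjusted p = 0.0065), Psmb9, a subunit of the immunoproteasome (-0.84, SE 0.13, adjusted p = 0.037), and the transcriptional corepressor Tle3 (-0.45, SE 0.07, adjusted p = 0.038). The remaining Tle3 probes differed by -0.44 and -0.33 and did not pass in limma (adjusted p = 0.072 and 0.118). Ctsc, the lysosomal protease cathepsin C, was lower on each of its 3 probes (-1.34, -1.21 and -1.40, adjusted p from 0.017 to 0.034). For every one of the 8 probes, the 7 anti-Sm arrays all lay on 1 side of the anti-PtC mean.

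Within slide 1 and slide 2 of these 14 arrays, the difference was 7.47 and 6.51 for H2-Ea, 1.91 and 2.59 for that H2-K1 probe, -1.27 and -0.85 for Eps8, -1.07 and -0.61 for Psmb9, and -0.60 and -0.31 for Tle3. With slide as a block, Psmb9 and Tle3 no longer passed (adjusted p = 0.055 for both in limma). With each of the 14 arrays left out in turn, H2-Ea, that H2-K1 probe and Eps8 passed in 14 of 14 runs, the Ctsc probes in 11, 5 and 4, and Psmb9 and Tle3 in 3 each. On the 5 anti-PtC arrays with the lowest H2-Ea signal, between 5.79 and 6.16, the probe's intensity before normalization was 0.889 to 1.06 times the array's median, so the size of its difference is limited by the floor of the arrays. The 2 dim arrays, normalized with the others, read 10.60 and 10.61 for the H2-K1 probe, against 9.39 to 10.58 on anti-Sm and 7.48 to 8.42 on the other anti-PtC arrays. Their Psmb9 signal was 9.50 and 9.01, against 10.24 to 10.97 on the other anti-PtC arrays and 9.40 to 10.10 on anti-Sm, and their Tle3 signal was 6.29 and 5.90, against 7.07 to 7.32 and 6.60 to 6.93. The Ctsc probe ILMN_1238486 read 7.70 and 6.46 on them, against 8.62 to 9.12 on the other anti-PtC arrays and 6.89 to 8.23 on anti-Sm. Their Eps8 signal was 6.94 and 6.36, against 6.78 to 7.51 on the other anti-PtC arrays and 5.89 to 6.50 on anti-Sm.

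**Figure D2:**
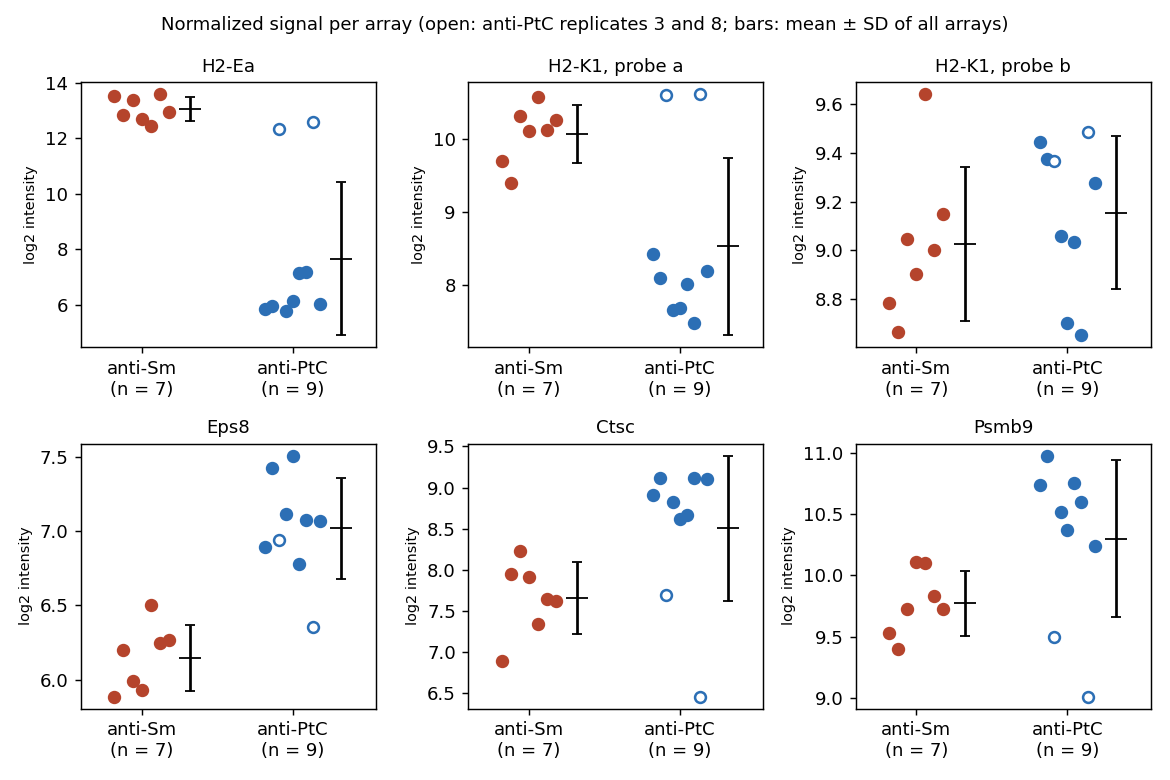
Normalized log2 intensity of H2-Ea, 2 probes of H2-K1 (a is ILMN_2795520), Eps8, Ctsc (ILMN_1238486) and Psmb9 on each array, anti-Sm (n = 7) in red and anti-PtC (n = 9) in blue, with the mean ± SD of all arrays of a group beside the points. The open circles are the dim anti-PtC replicates 3 and 8, which read 12.32 and 12.58 for H2-Ea while the other 7 anti-PtC arrays lie between 5.79 and 7.19.

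Of 26 gene lists fixed before the data were examined, camera (limma) with its preset inter-gene correlation called 8, of which 6 were higher and 2 lower in anti-Sm leukemias. None of the 8 calls held with an estimated correlation (smallest adjusted p = 0.527), and none with fry or an exact two-sided permutation of the list mean per array (smallest adjusted p = 0.512 and 0.0989). Without the 2 dim arrays camera called 7 lists, 6 of these 8 and the erythroid markers, and no longer called oxidative phosphorylation or stroma and endothelium. Regrouping the arrays gave 8 or more called lists in 33 of 100 splits, the real one included. The list differences below are therefore descriptions of these arrays.

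Plasma cell genes, which serve antibody secretion and protein folding, were higher in anti-Sm leukemias for 18 of 18 members, 8 of them at an unadjusted p under 0.05 and 0 when adjusted over all genes or adjusted over the list alone. Their mean difference was 0.50 (camera adjusted p = 2.98e-09, and adjusted p = 0.527 with an estimated correlation). It was 0.48 within slide 1, 0.61 within slide 2 and 0.55 with slide as a block. The members with the smallest p were Fkbp11, a prolyl isomerase of the secretory pathway (1.31, SE 0.41), Creld2, an endoplasmic reticulum stress protein (0.99, SE 0.34), and Ssr4, a subunit of the translocon complex (0.58, SE 0.21). The list mean was not high on every anti-Sm array: replicates 2, 4, 5 and 7 lay between 0.45 and 1.16 and replicates 1, 3 and 6 between -0.38 and -0.24, against -0.67 to 0.17 on the anti-PtC arrays. The exact permutation test of this list mean gave p = 0.0425 (adjusted p = 0.368).

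Cell cycle genes were higher in anti-Sm leukemias for 27 of 27 members, 5 at an unadjusted p under 0.05, with a mean difference of 0.45 (camera adjusted p = 1.33e-09, and adjusted p = 0.796 with an estimated correlation). Mcm5 (0.84, SE 0.34), Mcm2 (0.64, SE 0.27) and Mcm6 (0.67, SE 0.29), subunits of the replicative helicase, had the smallest p. The remaining Mcm6 probes differed by 0.60 and 0.10. The difference in the list mean was 0.85 within slide 1, 0.10 within slide 2 (camera adjusted p = 0.319) and 0.49 with slide as a block. The lowest list means were those of anti-PtC replicates 1 and 3 (-1.19 and -1.16), and without the 2 dim arrays the difference was 0.30, with 0 of 27 members at an unadjusted p under 0.05.

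MYC targets and ribosome biogenesis genes were higher for 19 of 21 members, by 0.16 on average (camera adjusted p = 0.0011, and adjusted p = 0.796 with an estimated correlation), among them Bop1 (0.39, SE 0.13), Npm1 (0.32, SE 0.14) and Fbl (0.29, SE 0.14). Within slide 1 the list differed by 0.39, within slide 2 by -0.07, and with slide as a block by 0.17. With median scaling in place of quantile normalization it differed by 0.45. That setting also raised lists that were not called, such as glycolysis, from a mean difference of 0.02 to 0.28. T cell markers hardly moved (0.17 and 0.18), and the larger values cannot be read as particular to the called lists. With quantile normalization but without anti-PtC replicate 1, the mean difference of the MYC list was 0.09 (camera adjusted p = 0.0314). Immediate early and BCR-induced genes were higher for 22 of 27 members, by 0.29 on average (camera adjusted p = 0.0175, and adjusted p = 0.817 with an estimated correlation), with Ier3 (0.72, SE 0.27), Ccnd2, cyclin D2 (0.85, SE 0.33), and the chemokine Ccl4 (0.76, SE 0.40, and 0.33 on its other probe) at the smallest p. The difference was 0.42 within slide 1 (camera adjusted p = 0.0857), 0.22 within slide 2 and 0.32 with slide as a block. With median scaling, which also raised lists that were not called, it was 0.56. Anti-PtC replicate 4 had a list mean of -1.56, and without it the mean difference was 0.11 (camera adjusted p = 0.426). The adjusted p was 0.0560 without anti-Sm replicate 6 and 0.0966 without anti-PtC replicate 7.

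MHC class II and co-stimulation genes were higher in anti-Sm leukemias for 11 of 14 members, with a mean difference of 0.59 and a median of 0.20 (camera adjusted p = 0.0010, and adjusted p = 0.796 with an estimated correlation). Without H2-Ea the mean difference of the other 13 members was 0.22 (camera adjusted p = 0.0175). Adjusted over the list alone, 2 members passed in limma, H2-Ea and H2-Ab1, against 0 over all genes tested. H2-Ab1, the beta chain of I-A, differed by 0.55 (SE 0.17) on the probe that stands for it and by -0.17 to 0.43 on its other 3 probes. H2-DMb2, part of the peptide exchange factor H2-M, differed by 0.55 (SE 0.25). The list differed by 0.80 within slide 1, 0.38 within slide 2 (camera adjusted p = 0.525) and 0.60 with slide as a block, H2-Ea included. Without H2-Ea it differed by 0.43 within slide 1, 0.01 within slide 2 (camera adjusted p = 0.869) and 0.23 with slide as a block. The call ended with cyclic loess normalization (camera adjusted p = 0.150). The exact permutation of the list mean gave p = 0.0047 (adjusted p = 0.0989) with H2-Ea and p = 0.242 without it. The values without H2-Ea were added after seeing the data.

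Oxidative phosphorylation genes were higher for 23 of 26 members, by 0.09 on average (camera adjusted p = 0.0304, and adjusted p = 0.817 with an estimated correlation). Ndufa2 (0.19, SE 0.12), Cox6c (0.32, SE 0.20) and Cyc1 (0.28, SE 0.18) had the smallest p and none was under 0.05. The list differed by 0.09 within slide 1 (camera adjusted p = 0.164), 0.12 within slide 2 and 0.10 with slide as a block, and camera no longer called it without the 2 dim arrays (adjusted p = 0.491), where 15 members were higher and 11 lower, with a mean difference of 0.05 and a median of 0.008. The call also ended when any of anti-Sm replicates 4, 5 and 6 or anti-PtC replicates 1, 3, 8 and 9 was left out (camera adjusted p from 0.0766 to 0.151). Cyclic loess normalization (camera adjusted p = 0.627, mean difference 0.03) and the filter at the 75th percentile (camera adjusted p = 0.138) ended it too. With median scaling, which also raised lists that were not called, the mean difference was 0.42.

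Markers of platelets and of stroma and endothelium were lower in anti-Sm leukemias. All 5 platelet markers were lower, by a mean difference of -0.31 (camera adjusted p = 0.0348, and adjusted p = 0.796 with an estimated correlation), among them the chemokines Ppbp (-0.64, SE 0.32, and -0.42 on its other probe) and Pf4 (-0.26, SE 0.20) and the receptor subunit Gp9 (-0.31, SE 0.21). On the anti-Sm arrays Ppbp read 5.70 to 5.99, Pf4 5.75 to 6.03 and Gp9 5.91 to 6.32, near the floor of the arrays. The platelet list mean was 1.58 on anti-PtC replicate 1 and 0.50 on replicate 4, against -0.24 to 0.12 on the other 14 arrays. Without replicate 1 the difference in that list mean was -0.13, without replicate 4 it was -0.26 and without both it was -0.05, comparisons added after seeing the data. In the camera runs without either of these arrays the list had too few members above the filter and was not tested. It differed by -0.60 within slide 1, by -0.08 within slide 2 (camera adjusted p = 0.612) and by -0.35 with slide as a block. The platelet call ended when any of anti-Sm replicates 3, 4, 6 and 7 or anti-PtC replicate 8 was left out (camera adjusted p from 0.0560 to 0.0771). All 7 stromal and endothelial markers were lower, by a mean difference of -0.29 (camera adjusted p = 0.0322, and adjusted p = 0.527 with an estimated correlation), among them the matrix protein Sparc (-0.94, SE 0.44, and -0.63 on its other probe), the endothelial receptor Pecam1 (-0.30, SE 0.20, and -0.18) and the collagen chain Col1a2 (-0.11, SE 0.09). Without the 2 dim arrays Col1a2 differed by -0.02 and Sparc by -1.51. On the dim replicate 8 Col1a2 read 6.72, against 5.99 to 6.21 on the other 15 arrays, also near the floor. The stromal list differed by -0.31 within each slide and with slide as a block, and was not called within either slide (camera adjusted p = 0.157 and 0.260) or without the 2 dim arrays (adjusted p = 0.234, 5 of 7 lower). That call also ended when any of anti-Sm replicates 4 and 6 or anti-PtC replicates 4 and 8 was left out (camera adjusted p from 0.0547 to 0.118), and cyclic loess normalization ended both calls (0.0680 for platelets and 0.204 for stroma). Both also ended with no filter on dim probes (0.0581 and 0.164), and the stromal call with array weights (0.181).

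**Figure D3:**
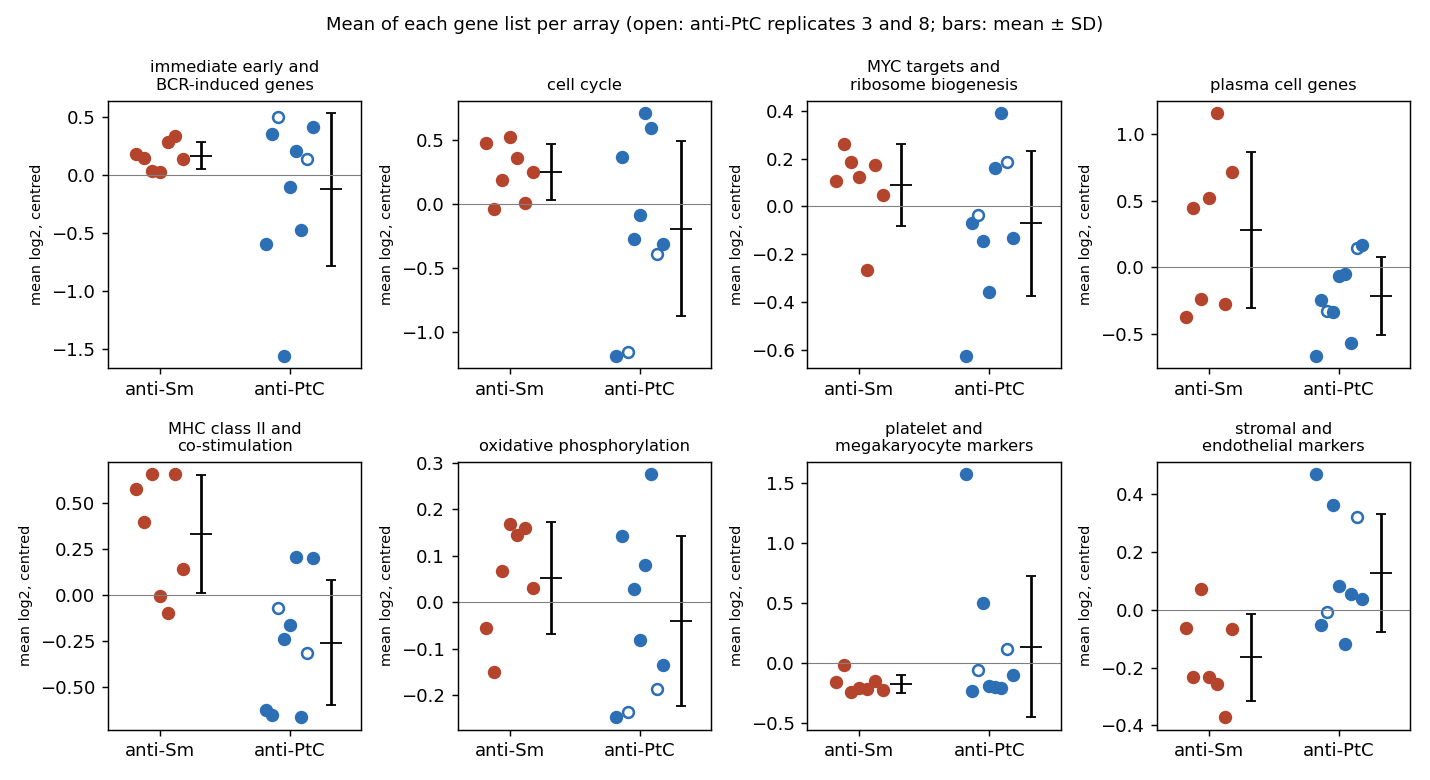
Mean log2 intensity per array of the 8 gene lists called by camera, centred on 0 for each gene over all arrays, anti-Sm (n = 7) in red and anti-PtC (n = 9) in blue, with mean ± SD beside the points. The open circles are the dim anti-PtC replicates 3 and 8. The list means of the 2 groups overlap in every panel, and those of the plasma cell genes reach from -0.38 to 1.16 in anti-Sm leukemias.

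The immediate early and BCR-induced genes, given above, were called (camera adjusted p = 0.0175, and 0.817 with an estimated correlation). The other lists close to BCR signalling were not called in the main setting over 16 arrays. Activating BCR signalling genes were higher for 8 and lower for 11 members (camera adjusted p = 0.443), with Malt1 the only member past the threshold when adjusted over the list alone. With median scaling the median difference of the activating list was 0.24 and camera's direction was up (camera adjusted p = 0.808), against -0.08 and down in the main setting. Median scaling also raised the median difference of the inhibitory list, from -0.06 to 0.07, and of the Toll-like receptor list, from 0.02 to 0.15. The turn is therefore not particular to the activating list. Inhibitory BCR signalling genes were higher for 4 and lower for 10 (0.220), anergy-associated genes for 3 and 6 (0.665), NF-kB target genes for 14 and 4 (0.125), Toll-like receptor signalling genes for 10 and 8 (0.775), and BCL2 family genes for 7 and 4 (0.704). Type I interferon response genes were higher for 16 and lower for 5 (0.0526), with Isg20 past the threshold when adjusted over the list alone. Alternatives gave calls for 3 of these lists. The inhibitory list was called lower with slide and position (camera adjusted p = 0.0363) and with array weights (0.0454), and the NF-kB list higher with median scaling (0.0211), with slide and position (0.0419), on slide 2 alone (0.0429) and without any of anti-Sm replicate 1 and anti-PtC replicates 2 and 9 (0.0227 to 0.0408). The interferon list was called higher on slide 2 alone (0.0429) and without any of anti-Sm replicates 1, 5 and 7 and anti-PtC replicates 1, 2 and 4 (0.00023 to 0.0355). Cd5, an inhibitory receptor typical of this leukemia, differed by -0.08 (SE 0.16) and lay above the anti-PtC mean on 3 of 7 anti-Sm arrays. Both probes of mouse Tcl1 lay below the filter on dim probes, between 5.70 and 6.24 on every array, and whether they read the transgene was not tested. Ighm and Ighd were not analysed here.

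Among B cell subset lists, B-1 cell genes were higher for 7 and lower for 8 members (camera adjusted p = 0.847), follicular genes for 4 and 3 (0.610) and marginal zone genes for 3 and 3 (0.778). Adhesion and trafficking genes were higher for 8 and lower for 9 (0.610), glycolysis genes for 8 and 6 (0.610), and heat shock genes for 2 and 5 (0.610). Without the 2 dim arrays heat shock genes were higher for 5 and lower for 2. Markers of other cell types were not called in the main setting either: T cells were higher for 12 and lower for 1 member (0.416), NK and cytotoxic cells for 4 and 1 (0.498), monocytes and macrophages for 7 and 7 (0.847), neutrophils for 10 and 3 (0.610), and erythroid cells for 6 and 2 (0.186). Without the 2 dim arrays T cell markers were higher for 3 and lower for 10 (0.553), and they were called higher without anti-PtC replicate 1 (0.0224). The erythroid list was called without the 2 dim arrays, higher for 8 of 8 members (camera adjusted p = 0.0148, and adjusted p = 0.691 with an estimated correlation). It was also called on slide 1 alone (0.0034), with median scaling (0.0172), with no filter (0.0216), with slide and position (0.0419), without anti-PtC replicate 8 (0.0052) and without anti-Sm replicate 5 (0.0477), while on slide 2 alone its mean difference was -0.05. The median difference of the B-1 and of the adhesion list was below 0 (-0.03 and -0.003) while the mean was above 0 (0.12 for both) and camera's direction was up, and for the monocyte list the median and mean were -0.009 and -0.011 with camera's direction up.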

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

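The tests of array brightness and sample identity, and the splits with the pair chosen anew, were chosen after the result was seen.

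After normalization the 2 dim anti-PtC arrays, replicates 3 and 8, carried H2-Ea near the anti-Sm level. Low brightness did not account for their excess over the other 7 anti-PtC arrays. Before any normalization the H2-Ea intensity was 2150 and 935 on the dim arrays, against 89.5 to 214 on those 7. H2-Ea stood at percentile 99.6 or higher among the probes of each dim array, against at most 77.4 on those 7. On the anti-Sm arrays the intensity before normalization was higher still, 5940 to 15105. Relative to the array's median it was 65.6 to 160 there, against 27.1 and 13.0 on the dim arrays. The nearness to the anti-Sm level was therefore seen only in ranks and normalized values, where low brightness was not excluded as its source. Normalization keeps the rank within an array, so the percentile restates the normalized values. Mislabelled and correctly assigned samples cannot be told apart here, and poor sample quality, which was not tested, stays open as well: the heat shock list mean was 2.41 and 2.36 on these arrays, against -0.94 to 1.60 on the other 14. Positions were taken on the 50 bright genes outside the MHC region with the smallest p over the other 14 arrays. On this scale 0 is the anti-PtC mean and 1 the anti-Sm mean. The mean position of the dim arrays was 0.990, but replicate 3 lay at 0.54 and replicate 8 at 1.44. Arrays left out in turn spread from 0.13 to 0.94 in anti-PtC (mean 0.39). In anti-Sm they spread from 0.38 to 0.96 (mean 0.74), so the groups overlapped. A difference in MHC haplotype between the mice also stays open, since some haplotypes are known to lack H2-Ea expression and a sequence variant under 1 of the H2-K1 probes may make its probes disagree: 2 of 96 other MHC-region genes (Psmb9 and Abhd16a) against 42 of 8750 genes elsewhere had p under 0.001 over 14 arrays (odds ratio 4.41, interval 0.51 to 17.4, Fisher's exact two-sided p = 0.0822), and the effect of the BCR itself was not tested apart from it.

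The MHC-region gene H2-Q5 was looked up after its values were seen. Over 14 arrays it was higher in anti-Sm leukemias by 1.53 (SE 0.42, limma adjusted p = 0.300). It read 7.61 to 8.62 on the anti-Sm arrays, 9.14 on anti-PtC replicate 1, 8.67 and 8.49 on the dim replicates 3 and 8, and 6.16 to 6.54 on the other 6 anti-PtC arrays. In limma it passed on slide 2 alone of the 14 arrays (2.25, adjusted p = 0.0053) and without anti-PtC replicate 1 (1.95, adjusted p = 6.3e-05).

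No probe passed over 16 arrays and 8 passed without the 2 dim arrays. None (0) of the 35 other pairs of anti-PtC arrays, left out in their place, gave as many, and the highest was 7, without replicates 6 and 8. The count hung on replicate 8: the 7 pairs of it with a brighter array gave 2 to 7 probes, and all 28 pairs that kept it in gave 0, those without replicate 3 included. Over 14 arrays, 1 of 100 splits, the real one, gave 8 or more probes, and the highest other split gave 2, but all these splits keep the choice of arrays, which was made after seeing the data, so they decide nothing about chance. With the left-out pair chosen anew in each split of the 16 arrays, as the pair of the group of 9 that gave the most probes in ordinary t tests, the real split took the 2 dim arrays and gave 8. In that test 2 of 100 splits, the real one included, gave as many (highest other 11). A split could leave out a dim array only where it fell in the group of 9. The real count hung on leaving out replicate 8, so the splits are not comparable and decide nothing about chance for that count. Over 16 arrays every split reaches a real count of 0 (100 of 100, highest other 3), so the splits decide nothing about chance there.

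The 8 gene lists called by camera over 16 arrays were matched or exceeded in 33 of 100 splits, the real one included. The highest other split called 16 lists and the median of the others was 6, so chance cannot be excluded for that count.

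Single arrays stood apart from the rest of their group in 9 of 100 groups of values examined. Chance alone gives about 1 in 20 for independent, normally distributed values. These groups share arrays and related genes, so this count cannot be judged against that rate. The ratio given is the gap to the nearest array over the range of the group. This rule looks for 1 array, so 2 arrays that lie together can hide each other. It did not flag the dim anti-PtC replicates 3 and 8 for brightness or for H2-Ea. Among anti-Sm arrays, replicate 4 was highest for Mcm5 (11.19, ratio 0.785), replicate 3 for H2-Ab1 (13.74, ratio 0.573) and replicate 2 for Gp9 (6.32, ratio 0.571). Among anti-PtC arrays, replicate 1 was highest for Pf4 (7.45, ratio 0.508), replicate 8 was highest for Col1a2 (6.72, ratio 0.756) and lowest for the Ctsc probe ILMN_3008859 (6.21, ratio 0.526). For list means, anti-Sm replicate 5 was lowest for MYC targets and ribosome biogenesis (-0.27, ratio 0.594), and the platelet markers were highest on anti-Sm replicate 2 (-0.02, ratio 0.573) and on anti-PtC replicate 1 (1.58, ratio 0.595).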

How the results depend on the processing

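The runs without the 2 dim arrays, at the 75th percentile, with exact permutation and all those over 14 arrays were chosen after seeing the data. The fold threshold acted on a fit with 0 calls, so its count was fixed at 0 in advance. With it included, the count of 0 probes and 0 genes held in 26 of 32 alternatives each. It became 2 probes and 2 genes with median scaling (H2-Ea and the H2-K1 probe ILMN_2795520), 2 probes and 1 gene on slide 1 alone (Dapk2 and an unnamed probe), 6 probes and 5 genes with array weights (H2-Ea, H2-K1, Eps8, Dapk2, Tedc1 and an unnamed probe), and 8 probes and 6 genes without the dim arrays. Leaving out each array in turn gave 0 to 2 probes and 0 to 2 genes: 1 without anti-PtC replicate 3 (H2-Ea) and 2 without replicate 8 (H2-Ea and Eps8). These genes other than H2-Ea and Eps8 were named after their values were seen.

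The count of called lists, 8 over 16 arrays, became 4 with cyclic loess, 5 at the 75th percentile (20 lists tested), 5 on slide 2 alone (3 of the 8, with NF-kB targets and interferon response), 10 with median scaling, 11 with slide and position, and 0 with an estimated correlation, 0 with fry and 0 with exact permutation. With arrays left out the count ran from 4 to 10 (4 without anti-Sm replicate 6, 5 without anti-Sm replicate 4). On slide 2 alone the MYC list turned to lower in anti-Sm (adjusted p = 0.743, not called), while Pf4 (0.0058) and Pecam1 (0.066) turned to higher, as did Cd5 (0.023) with median scaling. Plasma cell genes kept their camera call in 17 of 20 alternatives, cell cycle in 16, and both in 16 of 16 with an array left out. Oxidative phosphorylation kept it in 13 of 20 and 9 of 16.

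The 8 probes over 14 arrays became 5 with no filter, 5 with slide and position, 3 on slide 1 alone, 3 on slide 2 alone and 14 with array weights. With arrays left out they ran from 3 to 16: 3 without anti-Sm replicate 6 or 7 or anti-PtC replicate 2, 4 without anti-PtC replicate 4, 5 without anti-PtC replicate 1 or anti-Sm replicate 4, 14 without anti-Sm replicate 3 and 16 without anti-PtC replicate 6. Of the 28 alternatives, H2-Ea passed in 28, that H2-K1 probe in 27, Eps8 in 25, the Ctsc probes in 23, 15 and 14, Psmb9 in 11 and Tle3 in 9. Single slides hold fewer samples; for the other changes the cause was not tested. No paired analysis was possible because the labels give no replicate numbers shared between groups. The planned filter on detection p-values was not run, and without them signal over background cannot be given per probe.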

Other observations

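Heat shock genes varied between single leukemias far more than between the groups, whose list means differed by -0.28 over 16 arrays and by 0.38 without the 2 dim arrays. The mean of the 7 measured members, among them the chaperones Hspa1a, Hsph1 and Dnajb1, was 2.41 and 2.36 (log2, centred) on the dim anti-PtC replicates 3 and 8 and 1.60 on anti-Sm replicate 2. It lay between -0.94 and 0.37 on the other 13 arrays. T cell markers also varied widely, with list means of 1.24 on anti-PtC replicate 1 and -1.08, -1.02, -0.91 and -0.76 on anti-PtC replicates 3, 7, 8 and 6, against -0.44 to 0.79 on the anti-Sm arrays. Erythroid markers ranged from -1.41 on anti-PtC replicate 5 to 1.83 on the dim replicate 8 and 1.57 on anti-Sm replicate 1.

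Sex-linked genes, whose list had too few members to be tested, split the arrays in both groups. The Y-linked gene Eif2s3y read 8.08 and 8.25 on anti-Sm replicates 4 and 7, 8.47 and 8.00 on anti-PtC replicates 2 and 9 and 6.90 on anti-PtC replicate 1, against 5.75 to 5.89 on the other 11 arrays. The brighter Xist probe read 5.98 to 6.54 on those 5 arrays. On anti-Sm replicate 3 and anti-PtC replicate 6 it read 6.27 and 6.20 with Eif2s3y at 5.83 and 5.79, so neither gene was high there. On the remaining 9 arrays the Xist probe read 6.85 to 7.53.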
